A study of Homo sapiens with 3 samples.

How the data were processed

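Circular RNA (circRNA) was measured in 3 human cell lines with 1 library each: SV-HUC-1, an immortalized urothelial line, and J82 and T24, which the labels class as bladder cancer lines. Per the labels' protocols, libraries were made from 2 μg of total RNA after removal of ribosomal RNA. Linear RNA was digested with the exonuclease RNase R before fragmentation and directional cDNA synthesis, so the libraries carry little information on the linear transcripts of the host genes. RNase R digests circRNAs and linear RNAs to different degrees, and its yield was not measured here.

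The authors deposited 1 table of circRNAs with their position, circBase and circBank IDs, host gene and CPM (reads scaled to a common library size) in each line, named by the authors as normalized with TMM factors. Per the submitters' processing notes, the genome build was hg19, and Bowtie2 2.1.0, RSEM 1.2.15, STAR and edgeR were used, with no role or order stated for each. The tool that called back-splice junctions is not given in the sources used here, nor is whether a start position is counted from 0 or from 1. Positions below are therefore on hg19 as the table gives them. All 3 value columns were matched to a line by name, and 0 value columns stayed unmatched. The column for SV-HUC-1 spells that name with a small difference in its letters.

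Every CPM value in each column was a whole multiple of the column's smallest value above 0, with a tolerance of 0.01 reads, so 100% of the values came out as whole reads. One read was worth 0.0201 CPM in SV-HUC-1, 0.0211 in J82 and 0.0234 in T24. These steps correspond to TMM-scaled library totals of 49830000, 47300000 and 42720000 reads to 4 significant digits, far above the reads assigned to the listed circRNAs, so the denominator covers more than the circRNA reads. Each listed circRNA had at least 5 reads in at least 1 library, so circRNAs below that level were not analysed here.

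With 1 library per line there is no replicate spread, and no difference between lines has a replicate check. The comparisons fixed before the data were examined were J82 against SV-HUC-1, T24 against SV-HUC-1, both cancer lines against SV-HUC-1, and J82 against T24. Folds were computed as the difference of log2(CPM + 0.0234), where the pseudocount is 1 read in the shallowest library, so they understate the differences of circRNAs with few reads. A circRNA entered a comparison when it had at least 10 reads in at least 1 of the libraries compared, and it was counted as higher or lower from a 2-fold difference (1 on the log2 scale). Ratios in the text are ratios of CPM with exact 95% counting intervals (Clopper-Pearson on the reads of the 2 libraries). Where a library had 0 reads, the ratio was computed against a floor of 3 reads in that library and is given as "at least", rounded to the nearest digit printed. It leaves out the counting error of the other library, so it is not a 95% limit, and the exact 95% limit is lower. Reads carry no molecular identifiers, so intervals cover counting error only, and floors only that of the library with 0 reads.

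An exact binomial test of the reads (two-sided, Benjamini-Hochberg adjusted p under 0.05) was run as an alternative. It compares these 2 libraries, not the conditions. Both cancer lines were also set against SV-HUC-1 with limma on the log2 values and, as an alternative added later, with edgeR's quasi-likelihood test on the recovered reads. In both, the lone SV-HUC-1 library is assumed to vary like the cancer lines, with 1 residual degree of freedom. Other alternatives were 2 other scalings, 2 other pseudocounts, no filter, a filter of 20 reads, a 4-fold threshold, and host genes in place of circRNAs. A filter of 30 reads over the 3 libraries and folds centred on their median were added after the data were seen. For the lists that share the SV-HUC-1 library, 100 sets of unchanged libraries were simulated. Their counts varied by Poisson error alone, so variation between preparations or cultures of a line is not in them.

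The rule for named circRNAs was fixed before the data were examined. It takes the 8 circRNAs highest and the 8 lowest in both cancer lines, ranked by the smaller of the absolute log2 folds, and then the 4 highest and 4 lowest of each cancer line not already named. It adds the 5 highest and 5 lowest of J82 against T24, the 5 most abundant in each line, a list of 23 circBase IDs, of which 20 matched with their host gene, and the circRNAs of RIMS1 and CCAR1. circRNAs of 1 chromosome and 1 gene tied to sex were not named, and some items that the rule names are not reported here. Of the 3 unmatched IDs, those of circMYLK and 1 ID of circUBAP2 were not among the listed circRNAs, and that of CDR1as was listed without a host gene.

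The table gave no annotated host gene for 257 circRNAs, which entered no host gene total even where the circBank ID names a gene. Reads and CPM were summed over the other circRNAs by host gene, and 11 lists of host genes fixed beforehand were described by their median log2 fold. The lists were chromatin regulators, cell cycle and DNA repair, growth factor and kinase signalling, adhesion, matrix and cytoskeleton, RNA binding, splicing and RNA decay, the ubiquitin pathway, epithelial and urothelial genes, mesenchymal genes, neuronal genes, blood and endothelial genes, and genes often mutated in bladder cancer. Each median is given with its percentile among 10000 random lists of the same size matched in 10 bins of mean CPM, as a description of these libraries. In each list the rule names the 2 host genes with the highest and the 2 with the lowest mean fold. Other members were named after their values were seen.

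The calculations were tested on simulated data with 200 changed circRNAs, each with at least 10 expected reads in every library before the change. Counts varied by Poisson error alone, and J82 and T24 were given the same fold. The real lines also differed from each other, so the shares below do not carry over to them. In the simulated J82 comparison of 3496 circRNAs, the 2-fold rule recovered 54% of circRNAs changed 2-fold and 100% of those changed 4-fold, and it passed 9.37% of unchanged ones. In the simulated T24 comparison of 3370 circRNAs these shares were 46%, 100% and 9.80%. In the simulated comparison of both lines with SV-HUC-1, over 3173 circRNAs, limma called 0% of circRNAs changed 2-fold, 27.1% of those changed 4-fold and 84% of those changed 16-fold. There edgeR called 42%, 93.75% and 100%. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.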

Results

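Circular RNA was profiled in SV-HUC-1, an immortalized urothelial cell line, and in the bladder cancer lines J82 and T24, with 1 RNase R-treated library per line. CircRNAs are covalently closed products of back-splicing, in which a downstream splice donor joins an upstream acceptor. The table listed 10562 circRNAs from 4231 host genes, of which 9109 (86.2%) had a circBase ID. Reads assigned to them came to 128055 in SV-HUC-1, 126041 in J82 and 108574 in T24. The numbers of circRNAs detected were 9392, 9332 and 8808, and 7383 (69.9%) were detected in all 3 libraries. When the deeper libraries were thinned to the 108574 reads of T24, 9247 ± 12.25 circRNAs (SD over 20 draws) remained detected in SV-HUC-1 and 9191 ± 12.8 in J82. The list itself holds circRNAs with at least 5 reads in at least 1 library at full depth, which favours the deeper libraries. Thinning therefore may not remove all of the effect of depth. PTK2, which encodes focal adhesion kinase, gave the most circRNAs (36), followed by TBCD with 29, TRIO with 24 and SMARCC1 with 22.

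The circRNA of CDYL, a chromodomain protein (hsa_circ_0008285, chromosome 6, 4891946 to 4892613, plus strand), led in SV-HUC-1 at 28.7 CPM and in J82 at 27.7 CPM, and stood at 10.8 CPM in T24. That of CAMSAP1, a microtubule minus-end binding protein (hsa_circ_0001900), was among the 5 most abundant in every line, with 16.1 CPM in SV-HUC-1, 18.3 in J82 and 18.6 in T24. In T24 the leading circRNA came from LPAR1, a lysophosphatidic acid receptor (hsa_circ_0087960), with 20.2 CPM against 4.17 in SV-HUC-1, a ratio of 4.83 (95% counting interval 4.15 to 5.65). The 10 most abundant circRNAs held 4.48%, 4.86% and 5.30% of the circRNA reads of SV-HUC-1, J82 and T24.

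The series title names circRIMS1, a circRNA of the gene for a presynaptic active zone protein, and CCAR1, a regulator of cell division and apoptosis. The circRNA with the circBase ID taken here for circRIMS1, hsa_circ_0132246 (chromosome 6, 73005639 to 73043538, plus strand), had 378 reads in T24 (8.85 CPM), 5 in J82 (0.106 CPM) and 0 in SV-HUC-1. It was at least 147-fold higher in T24 than in SV-HUC-1 and 83.7-fold (35.6 to 259) higher in T24 than in J82. With 5 reads, J82 stayed under the filter of 10 reads, and no excess over SV-HUC-1 was established there. Its ratio to the floor of 3 reads in SV-HUC-1 was 1.76, without the counting error of the 5 reads. The other 7 listed circRNAs of RIMS1 had between 5 and 11 reads in T24 and 0 in both other lines, so that the host gene reached 432 reads in T24, 5 in J82 and 0 in SV-HUC-1. The 3 circRNAs of CCAR1 together had 39 reads in SV-HUC-1, 29 in J82 and 52 in T24. Their ratio to SV-HUC-1 was 0.783 (0.467 to 1.30) in J82 and 1.56 (1.01 to 2.42) in T24. Circular reads do not measure the linear CCAR1 transcript.

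**Figure D1:**
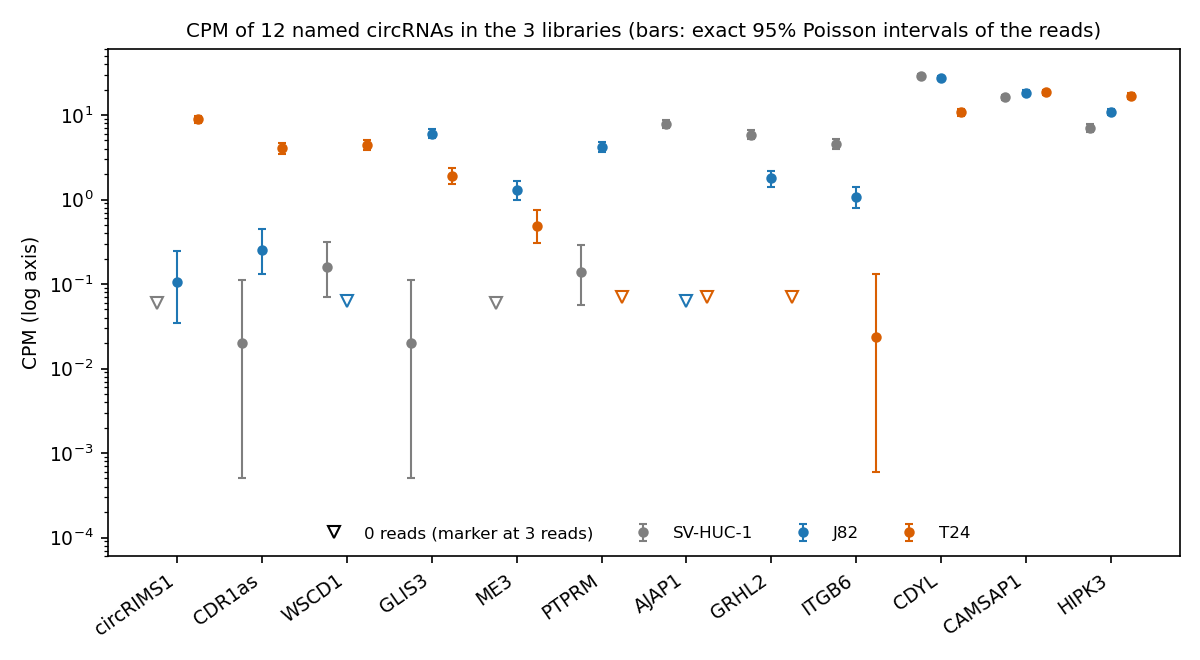
CPM of 12 named circRNAs in the 3 libraries on a log axis, with 1 point per library. Bars are exact 95% Poisson intervals of the reads, and open triangles mark libraries with 0 reads, drawn at the level of 3 reads. The circRNA of RIMS1 stands at 8.85 CPM in T24 with 0 reads in SV-HUC-1, whereas that of CAMSAP1 lies between 16.1 and 18.6 CPM in all 3 lines.

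In J82 against SV-HUC-1, the circRNA of GFRA1, a receptor for glial cell line-derived neurotrophic factor (hsa_circ_0005239), had 92 reads in J82 and 0 in SV-HUC-1. It was at least 32.3-fold higher. CircRNAs of INPP4B, a phosphoinositide phosphatase (hsa_circ_0125415), PARD3B, a cell polarity protein (hsa_circ_0004575), and CREB3L1, a membrane-bound transcription factor (hsa_circ_0007719), were at least 14.1-, 12.6- and 11.2-fold higher. In the opposite direction stood circRNAs of SMO and EVC2, both components of hedgehog signalling. That of SMO (hsa_circ_0001742) had 80 reads in SV-HUC-1, 0 in J82 and 41 in T24, and that of EVC2 (hsa_circ_0004228) had 77, 0 and 40. They were at least 25.3- and 24.4-fold lower in J82. CircRNAs of FHOD3, a formin (hsa_circ_0108363), and of MFI2, or melanotransferrin (no circBase ID, chromosome 3, 196742235 to 196743240, minus strand), were at least 12.02- and 9.49-fold lower in J82. In T24 they were lower as well, with 1 read against 38 in SV-HUC-1 for FHOD3 and 6 against 30 for MFI2.

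Of 3996 circRNAs compared, 916 were at least 2-fold higher and 932 at least 2-fold lower in J82, with a median log2 fold of -0.01. Simulated unchanged libraries of these depths, which here and below hold counting error alone, gave on average 152.1 and 182.5. The exact binomial test, which compares these 2 libraries and not the conditions, called 1388 circRNAs at any fold.

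Among circRNAs chosen beforehand by their circBase ID, that of FNDC3B (hsa_circ_0006156) was 6.19-fold (4.24 to 9.31) higher in J82 than in SV-HUC-1, with 188 against 32 reads. CircRNAs of RHOBTB3 (hsa_circ_0007444), RNF13 (hsa_circ_0001346), SMARCA5 (hsa_circ_0001445) and FBXW7 (hsa_circ_0001451) were 2.83-fold (2.40 to 3.35), 2.56-fold (1.86 to 3.56), 2.21-fold (1.51 to 3.27) and 2.16-fold (1.59 to 2.95) higher. CircRNAs of HIPK3 (hsa_circ_0000284), PVT1 (hsa_circ_0001821) and UBXN7 (hsa_circ_0001380) stayed within 2-fold, at 1.53 (1.33 to 1.76), 1.46 (1.24 to 1.73) and 1.71 (1.32 to 2.21). So did those of ASXL1 (hsa_circ_0001136), ZKSCAN1 (hsa_circ_0001727), FOXO3 (hsa_circ_0006404), CCDC66 (hsa_circ_0001313), SHPRH (hsa_circ_0001649) and TCF25 (hsa_circ_0041103), with ratios between 0.621 and 1.28.

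Summed over the circRNAs of a host gene, epithelial and urothelial genes stood lower in J82. Of 13 measured, 7 were at least 2-fold lower and KRT7 and PLEKHA7 at least 2-fold higher. LAMA3, a chain of the basement membrane laminin of epithelia, had 7 reads against 116 (15.7-fold lower, 7.40 to 40.0), and EPCAM, an epithelial adhesion molecule, had 8 against 45 (5.34-fold lower, 2.49 to 13.1). CDH1, which encodes E-cadherin, had 8 against 20 (2.37-fold lower, 1.001 to 6.23). The list's median log2 fold was -1.14, at percentile 0.36 of random lists. With CDH3 and ST14, which had 0 reads in J82, at their bound and ratios taken without the pseudocount, it was -1.25. Both medians are the value of CDH1, so the shift came from leaving out the pseudocount and not from the bounds. Of 3 measured neuronal genes, NRXN3 and ANKS1B were higher and RIMS2 lower. NRXN3, a presynaptic adhesion protein, had 47 against 4 reads (12.4-fold, 4.53 to 47.3). That list's median was 3.29 (percentile 99.8), and 1.95 with ANKS1B and RIMS2 at their bounds. KCNQ5 and CDR1 are on that list, but their named circRNAs had no annotated host gene and did not enter the median. Those of KCNQ5 had 29 and 25 reads in SV-HUC-1 and 0 in J82, and that of CDR1 had 1 and 12.

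The other lists lay inside the central 95% of random lists in J82. Of 8 mesenchymal genes, MYLK and BNC2 were higher and FN1, ROR1, COL5A1 and LTBP2 lower (median -0.63, percentile 8.57). The sign turned without the read filter, with a median of 0.25 (percentile 77.7) over 15 genes. FN1, which encodes fibronectin, had 6 reads against 73 and was 11.6-fold lower (5.06 to 32.5). Of 55 adhesion, matrix and cytoskeleton genes, 10 were higher and 9 lower (median 0.11, percentile 74.4). PARD3B had 73 reads against 2, a ratio of 38.5 (10.3 to 324). Of 57 cell cycle and DNA repair genes, 8 were higher and 8 lower (median 0.07, percentile 75.2). MDM2, the ubiquitin ligase that targets p53, had 51 reads against 8 and was 6.72-fold higher (3.16 to 16.4), whereas FANCI, of the Fanconi anaemia pathway, had 13 against 60 and was 4.38-fold lower (2.38 to 8.70). Of 50 growth factor and kinase genes, 9 were higher and 5 lower (median 0.07, percentile 68.4). FGFR1 had 38 reads against 1, a ratio of 40.0 (6.76 to 1622), and FGFR2 had 17 against 87 and was 4.86-fold lower (2.87 to 8.72).

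Chromatin regulators had 4 of 49 host genes higher (KAT6A, DOT1L, KDM4B and SMARCA5) and 4 lower (ASXL2, HDAC4, SMARCA2 and KDM5A), with a median of -0.05 (percentile 34.1). The interval of KDM5A took in 1 (ratio 0.434, 0.152 to 1.10). Of 47 RNA binding, splicing and decay genes, 6 were higher and 3 lower (MSI2, CSTF3 and R3HCC1L; median 0.03, percentile 59.1). There CNOT2, a subunit of the CCR4-NOT deadenylase complex, had 208 reads against 26 and was 8.43-fold higher (5.59 to 13.2). Of 55 ubiquitin pathway genes, 9 were higher and 6 lower (median 0.04, percentile 63.6), and USP3 was 5.42-fold higher (3.37 to 9.11). Of 22 genes often mutated in bladder cancer, NFE2L2 was among those higher and ASXL2, TSC1 and SPTAN1 were lower (median 0.05, percentile 58.6). The intervals of NFE2L2 (ratio 2.74, 0.916 to 9.81) and TSC1 (0.316, 0.0559 to 1.23) took in 1. FLI1 was the 1 measured blood or endothelial gene, 2.85-fold lower (1.40 to 6.25; log2 -1.42, percentile 7.80), and without the filter the median of 2 such genes was 0.52.

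In T24 against SV-HUC-1, after circRIMS1, the highest named circRNA of T24 was hsa_circ_0001946, the circBase ID of CDR1as, a circRNA that binds miR-7 (chromosome X, 139865339 to 139866824, plus strand; host gene not annotated). It had 172 reads in T24, 12 in J82 and 1 in SV-HUC-1, a ratio of T24 to SV-HUC-1 of 200.6 (35.5 to 7969). A circRNA of TTC28 (hsa_circ_0003618) had 68 reads in T24, 25 in J82 and 1 in SV-HUC-1, a ratio of T24 to SV-HUC-1 of 79.3 (13.8 to 3178). One of the polarity gene PARD3 without a circBase ID (chromosome 10, 34661425 to 34667034, minus strand) had 68 reads in T24 and 0 in both other lines, and was at least 26.4-fold higher than in SV-HUC-1. Below SV-HUC-1, the lowest in T24 after that of AJAP1, described below, was a circRNA of GRHL2, an epithelial transcription factor (hsa_circ_0085173), with 292 reads in SV-HUC-1, 84 in J82 and 0 in T24, at least 83.5-fold lower in T24. The circRNA of the epithelial integrin gene ITGB6 (hsa_circ_0056856) had 1 read against 227, a ratio of 0.00514 (1.30e-04 to 0.0289). That of PPP1CB, a catalytic subunit of protein phosphatase 1 (hsa_circ_0119704), had 1 against 129, a ratio of 0.00904 (2.27e-04 to 0.0513). A circRNA of LAMA3 (hsa_circ_0047253) had 0 against 81 and was at least 23.2-fold lower. In J82, these circRNAs of ITGB6, PPP1CB and LAMA3 had 51, 7 and 4 reads and were also lower than in SV-HUC-1.

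Of 3847 circRNAs compared, 823 were at least 2-fold higher and 1051 at least 2-fold lower in T24, with a median log2 fold of -0.14. Simulated unchanged libraries gave on average 132.8 and 188.1, and the exact binomial test called 1440 circRNAs. Under median-of-ratios scaling the median was -0.15, and higher circRNAs made up 43.8% of those past 2-fold against 43.9% as deposited.

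Among the circRNAs chosen by ID, PVT1 was 2.89-fold (2.49 to 3.37) higher and HIPK3 2.38-fold (2.09 to 2.71) higher. HIPK2 (hsa_circ_0001756) had 14 against 7 reads, a ratio of 2.33 (0.881 to 6.83). CircRNAs of CDYL and CCDC66 were 2.65-fold (2.39 to 2.95) and 3.69-fold (2.00 to 7.36) lower, and that of TCF25, with 4 against 11 reads, had a ratio of 0.424 (0.0985 to 1.43). RHOBTB3, RNF13, SMARCA5, FBXW7, FNDC3B, UBXN7, ASXL1, ZKSCAN1, FOXO3 and SHPRH stayed within 2-fold, with ratios between 0.611 and 1.92. Those of ITCH (hsa_circ_0001141), MTO1 (hsa_circ_0007874) and SLC8A1 (hsa_circ_0000994) had under 10 reads in every line.

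All 12 measured epithelial and urothelial host genes were at least 2-fold lower in T24, 10 of them with 0 reads there. GRHL2 had 371 circular reads in SV-HUC-1 and 0 in T24 (at least 106-fold lower), LAMA3 116 and 0 (at least 33.2-fold) and MYO5B, a myosin of apical vesicle transport, 90 and 0 (at least 25.7-fold). EPCAM had 45 and 0, ESRP1, an epithelial splicing factor, 44 and 0, and CDH1 20 and 0, or at least 12.9-, 12.6- and 5.72-fold lower. PPARG had 25 reads against 65 (2.23-fold lower, 1.39 to 3.69). The median log2 fold was -4.73, below all 10000 random lists, and -3.08 with the host genes at 0 reads at their bound. Of 8 mesenchymal genes, ZEB1, NID1 and LTBP2 were higher and COL5A1, FN1 and ROR1 lower. ZEB1, a repressor of epithelial genes, had 16 reads against 2, a ratio of 9.33 (2.19 to 83.7), and COL5A1, a type V collagen chain, had 0 against 190 (at least 54.3-fold lower). That list's median was 0.32 (percentile 76.4) and its mean -0.76, and without the filter the median over 16 genes was -0.42 (percentile 22.8).

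**Figure D2:**
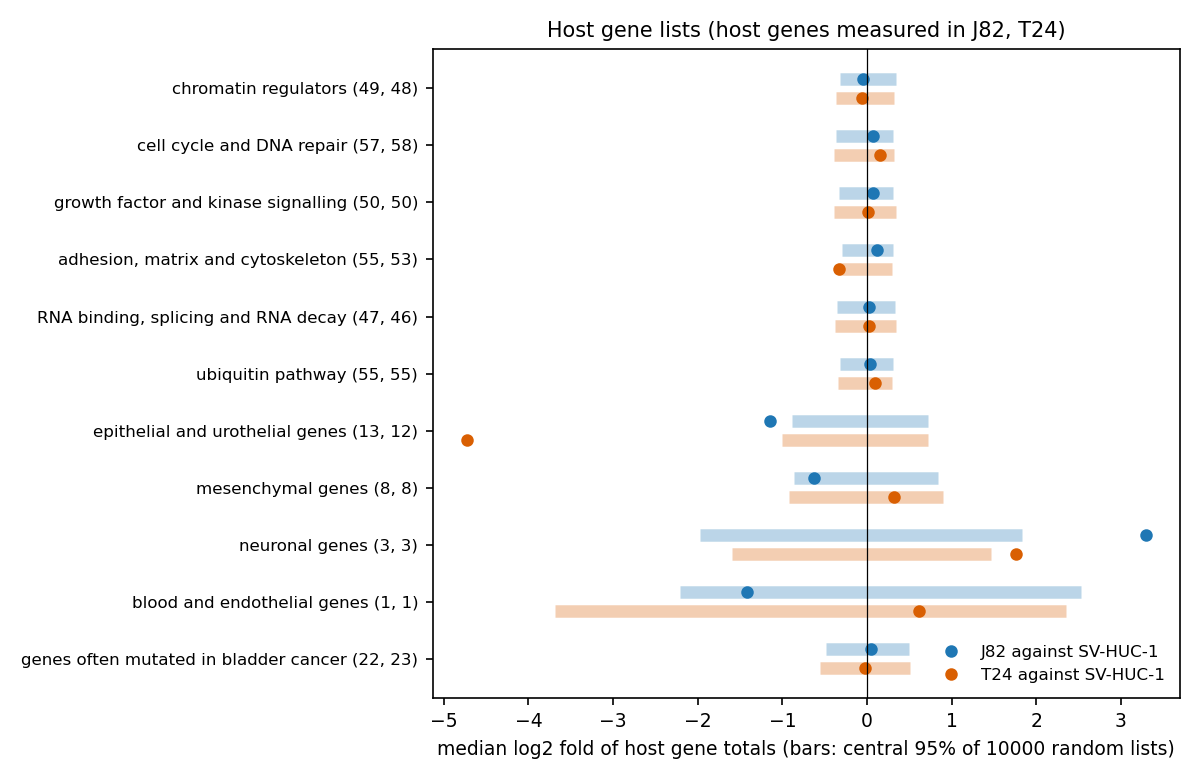
Median log2 fold of host gene totals in each of 11 lists, for J82 (blue) and T24 (orange) against SV-HUC-1, with the numbers of host genes measured in J82 and T24 in parentheses. Points are medians on the log2(CPM + pseudocount) scale and bars the central 95% of 10000 random lists matched on mean CPM. The epithelial and urothelial list lies below its bar in both lines, at -1.14 in J82 and -4.73 in T24, and the neuronal list, with 3 host genes measured in each line, above it. The neuronal list leaves out the named circRNAs of KCNQ5 and CDR1, which had no annotated host gene.

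Of 53 adhesion, matrix and cytoskeleton genes, 7 were higher and 20 lower in T24, with a median of -0.33 at percentile 2.90, and of -0.17 at percentile 11.9 without the filter (65 genes). SPECC1 had 14 reads against 191 (11.7-fold lower, 6.80 to 21.8), and NEDD9, a scaffold of focal adhesions, 0 against 32 (at least 9.15-fold lower). Without ITGB6 and LAMA3, which the epithelial list also holds, the median was -0.18 at percentile 12.9. FAT1 was 5.37-fold higher (2.67 to 11.9). Of the 3 neuronal genes measured, RIMS1 (432 reads against 0) and NRXN3 (14 against 4, ratio 4.08, 1.28 to 17.03) were higher, and RIMS2 had 22 against 16. The median was 1.76 (percentile 98.9), the value of NRXN3. With RIMS1 at its bound and ratios taken without the pseudocount it was 2.03, again that of NRXN3. That rise came from leaving out the pseudocount and not from the bound. Without RIMS1, the gene of the study's title, the median was 1.202 (percentile 90.5). As in J82, it leaves out the named circRNAs of KCNQ5 (0 reads in T24) and CDR1 (172 reads against 1), which had no annotated host gene.

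Of 58 cell cycle and DNA repair genes, 14 were higher and 7 lower in T24 (median 0.16, percentile 84.5). USP1, a deubiquitinase of the Fanconi anaemia pathway, had 27 reads against 3, a ratio of 10.5 (3.23 to 54.1), and BUB1B, a spindle checkpoint kinase, was 6.71-fold higher (2.29 to 26.7). Of 50 growth factor and kinase genes, 8 were higher and 9 lower (median 0.01, mean -0.06, percentile 57.3). FGFR2 had 0 reads against 87 (at least 24.9-fold lower), IGF1R 38 against 189 (4.27-fold lower, 3.00 to 6.21) and MAP3K5 98 against 18 (6.35-fold higher, 3.82 to 11.2). Of 46 RNA binding, splicing and decay genes, 9 were higher and 5 lower (ESRP1, MSI2, RBFOX2, UPF2 and CSTF3; median 0.03, mean -0.05, percentile 58.5). Chromatin regulators had 5 of 48 higher (KAT6B, DOT1L, KDM4B, BAZ1B and RSF1) and 9 lower (median -0.06, percentile 36.8), and ASXL2 was 6.43-fold lower (2.74 to 18.5). Of 55 ubiquitin pathway genes, 8 were higher and TRIM2, ZNRF2 and USP37 lower (median 0.09, percentile 75.7), and UBR1 was 12.8-fold higher (5.18 to 41.1). Of 23 genes often mutated in bladder cancer, FAT1, NFE2L2, ATM and PARD3 were higher and ASXL2, RXRA, SPTAN1, CHD6 and PPARG lower (median -0.02, mean 0.05, percentile 49.96). FLI1, the 1 blood or endothelial gene, had a ratio of 1.56 (0.968 to 2.52; percentile 76.4).

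Some circRNAs differed from SV-HUC-1 in the same direction in both cancer lines. A pair of circRNAs of GLIS3, a zinc finger transcription factor, were higher in both. The first (hsa_circ_0002874, chromosome 9, 4286037 to 4286523, minus strand) had 1 read in SV-HUC-1, 284 in J82 and 81 in T24, with ratios of 299 (53.3 to 11860) and 94.5 (16.5 to 3777). The other (hsa_circ_0006370) had 0, 52 and 14 reads. The circRNA of ME3, a mitochondrial malic enzyme (hsa_circ_0023966), had 0, 61 and 21 reads and was at least 21.4-fold higher in J82 and 8.16-fold in T24. CircRNAs of PVRL3, or nectin-3 (hsa_circ_0007315), ELL2, an elongation factor (hsa_circ_0006160), UBAP2L (hsa_circ_0006849) and, by its circBank ID, TTC28 (hsa_circ_0006776, host gene not annotated) had 0 reads in SV-HUC-1 and between 12 and 59 in the cancer lines.

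Lower in both was a circRNA of AJAP1, an adherens junction-associated protein (hsa_circ_0009438, chromosome 1, 4771959 to 4772759, plus strand), with 392 reads in SV-HUC-1 and 0 in both cancer lines. It was at least 124-fold lower in J82 and 112-fold in T24. The circRNA of SLC1A6, a glutamate transporter (hsa_circ_0109167), had 95 reads and then 0 and 0, at least 30.1- and 27.2-fold lower. One of COL5A1 without a circBase ID (chromosome 9, 137619111 to 137660309, plus strand) had 47, 0 and 0, and those of STAC (hsa_circ_0064809) and PLCXD3 (hsa_circ_0129066) had 31 and 21 reads in SV-HUC-1 and 0 in the others. A pair with no annotated host gene and circBank IDs of KCNQ5, a potassium channel (hsa_circ_0132255 and hsa_circ_0002930), had 29 and 25 reads in SV-HUC-1 and 0 in the cancer lines. Another, with a circBank ID of KIRREL3 (hsa_circ_0008111), had 46, 0 and 1. At the level of host genes, CDH1, CDH3, EPCAM, ST14, LAMA3, ITGB6 and MYO5B of the epithelial list and FN1, COL5A1 and ROR1 of the mesenchymal list were at least 2-fold lower in both lines. NRXN3 of the neuronal list, and BUB1B, NUSAP1, MDM2, PRKDC and USP1 of the cell cycle and DNA repair list, were at least 2-fold higher in both. ANAPC1, FANCI and MCM6 of the latter list were at least 2-fold lower in both. The intervals of ANAPC1 took in 1 in J82 (ratio 0.351, 0.0826 to 1.16) and in T24 (0.292, 0.0528 to 1.08). So did that of PRKDC in J82 (2.41, 0.937 to 6.92).

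Of 3330 circRNAs compared in both lines, 246 were at least 2-fold higher in both and 566 at least 2-fold lower in both. Simulated unchanged libraries that share SV-HUC-1 gave 26.0 and 48.4, and independent lists would share 54.1 and 294. Part of the excess over either may come from the shared SV-HUC-1 library. The surplus of lower circRNAs depended on the filter: among 2612 circRNAs with at least 30 reads over the 3 libraries, 235 were higher and 215 lower in both. Across circRNAs, which are not independent replicates, the folds of J82 and T24 had r = 0.646 against 0.544 in simulated unchanged libraries, and a covariance of 1.29 against 0.160, a difference of 1.13. With J82 and T24 as a pair against SV-HUC-1, limma called 0 circRNAs (lowest adjusted p 0.480, 300 at an unadjusted p under 0.05) and edgeR called 0 higher and 1 lower, AJAP1 (adjusted p 0.00579, 287 at an unadjusted p under 0.05).

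**Figure D3:**
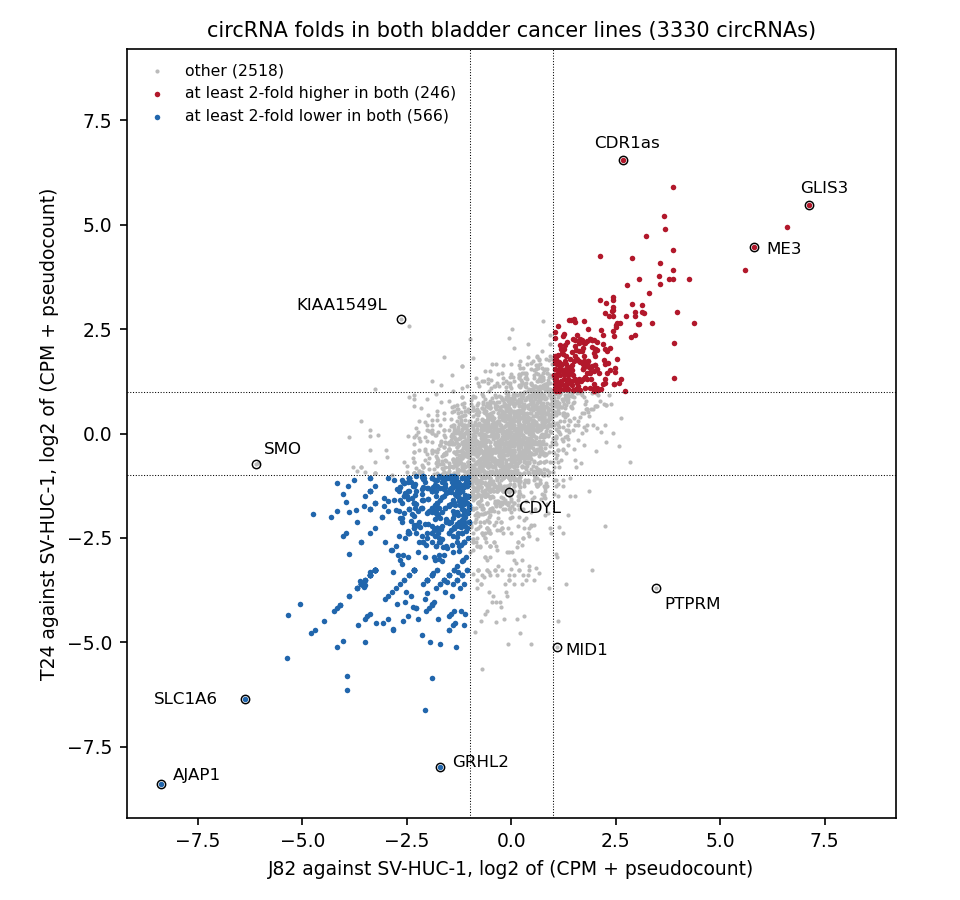
Log2 fold against SV-HUC-1 in J82 (x axis) and T24 (y axis), on the log2(CPM + pseudocount) scale, for the 3330 circRNAs compared in both. Red points are the 246 at least 2-fold higher in both lines and blue points the 566 at least 2-fold lower in both. Dotted lines mark 2-fold, and folds against a library with 0 reads depend on the pseudocount. The AJAP1 circRNA hsa_circ_0009438 lies lowest in both lines, and the GRHL2 circRNA hsa_circ_0085173 lies at -1.71 in J82 and -7.97 in T24. Another circRNA of GRHL2, hsa_circ_0085170, was 2.23-fold (1.36 to 3.75) higher in J82, and the host total of GRHL2 there had a log2 fold of -0.95.

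In J82 against T24, circRNAs of PTPRM, a receptor tyrosine phosphatase, had 197 and 159 reads in J82 and 0 in T24 (hsa_circ_0007144 and hsa_circ_0006114), and were at least 59.3- and 47.9-fold higher in J82. GRHL2 (hsa_circ_0085173) and MID1, a ubiquitin ligase of microtubules (hsa_circ_0007718), had 84 and 80 reads in J82 and 0 in T24, at least 25.3- and 24.1-fold higher. A circRNA of INPP4B (hsa_circ_0071037) had 56 and 0, at least 16.9-fold higher. Lower in J82 were circRNAs of WSCD1 (hsa_circ_0107325), with 0 reads against 190 in T24 (at least 70.1-fold), and of ZFPM2, a cofactor of GATA factors (hsa_circ_0003380), with 0 against 53 (at least 19.6-fold). That of PARD3 was at least 25.1-fold lower, and that of KIAA1549L (hsa_circ_0021609) had 3 reads against 156, a ratio of 0.0174 (0.00354 to 0.0517). The fifth was circRIMS1. Of 3679 circRNAs compared, 925 were at least 2-fold higher and 718 at least 2-fold lower in J82 than in T24, against 180.3 and 133.1 in simulated unchanged libraries.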

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

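The 3 circRNAs below were named by the rules fixed before the data were examined and lay at least 2-fold from SV-HUC-1 in opposite directions in J82 and T24. All 3 came from the 5 highest and 5 lowest of J82 against T24, so they were picked by the same difference that is reported for them. With 1 library per line, the difference between the lines was not tested across replicates. No explanation was tested for them.

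The circRNA of PTPRM with the ID hsa_circ_0006114 had 14 reads in SV-HUC-1, 159 in J82 and 0 in T24. It was 11.96-fold (6.92 to 22.4) higher in J82 and at least 4.001-fold lower in T24, and its log2 folds on the pseudocount scale differed by 7.18. The circRNA of MID1 (hsa_circ_0007718) had 39, 80 and 0 reads, 2.16-fold (1.46 to 3.26) higher in J82 and at least 11.15-fold lower in T24, a difference of 6.20. The circRNA of KIAA1549L (hsa_circ_0021609) had 26, 3 and 156 reads, with ratios to SV-HUC-1 of 0.122 (0.0236 to 0.397) in J82 and 6.998 (4.60 to 11.1) in T24, a difference of -5.40. In all, 23 circRNAs were at least 2-fold higher in J82 and lower in T24, and 12 the reverse.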

How the results depend on the processing

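The edgeR test, the filter of 30 reads over the 3 libraries and the centring on medians were chosen after seeing the data. Log2 folds of named circRNAs against SV-HUC-1 kept their sign. Of 22 list medians, 5 turned sign with no filter (mesenchymal and growth factor genes in both lines, blood genes in J82) and 2 with equal column sums (RNA binding and ubiquitin genes in J82), and each lay inside the central 95% of random lists. Of the main results under their alternatives, 48 values stayed within 1.5 times the main count and 40 did not. Of the single circRNAs, host genes and lists, 507 stayed within their counting interval or, for lists, on their side of the central 95% of random lists. The 1 exception was the adhesion list in T24, whose median of -0.31 with equal column sums lay at percentile 2.235. Both other scalings and both other pseudocounts kept every count of circRNAs past 2-fold within 1.5 times. The numbers below are circRNAs higher and lower in J82, in T24, in both cancer lines, and in J82 against T24, in that order. With no filter they were 2652 and 2617, 2598 and 2913, 1186 and 1538, and 2729 and 2478. A filter of 20 reads, which compares fewer circRNAs, gave 392 and 384, 329 and 446, 100 and 246, and 376 and 261. At a 4-fold threshold they were 360 and 320, 298 and 463, 62 and 156, and 370 and 246. Host genes, which are fewer, gave 488 and 516 in J82, 490 and 579 in T24, 292 lower in both, and 521 and 418 in J82 against T24. The exact binomial test left 584 lower in J82, 144 higher and 328 lower in both, and 477 lower in J82 than in T24. For both cancer lines as a pair, limma called 0 and 0, and edgeR 0 and 1. At least 30 reads over the 3 libraries left 215 lower and 235 higher in both, so the surplus of lower ones turned. In J82 the main counts were near even, and higher ones led with no filter, 20 reads, 4-fold, the exact test and both other pseudocounts. Leaving out a replicate and a paired fit do not apply, since no line has a replicate. No paired analysis was possible because each line has 1 library. Depth limits what can be seen: 0 reads allow up to 0.0602 CPM in SV-HUC-1, 0.0634 in J82 and 0.0702 in T24.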

Other observations

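The test of a chance arrangement of host genes over chromosomes, and the filter and centring applied to the circRNAs lower in both lines, were chosen after the result was seen. So were the genes named in this part.

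Some host genes had circular reads in 1 line and 0 in the others. In SV-HUC-1 these included AJAP1 with 397 reads from 2 circRNAs, SLC1A6 with 111 from 4 and STAC, an adaptor of voltage-gated calcium channels, with 57 from 3. In J82 they included NPAS3, a neuronal transcription factor, with 50 reads from 3 circRNAs, NLRP2 with 25 from 3, and BMPER, a modulator of BMP signalling, and PLCE1, a phospholipase C, with 24 each from 2. In T24 they included LOC284757 with 32 reads, EIF2B3 with 12 and HAVCR1, a kidney injury molecule, with 11. RIMS1 had 432 reads in T24, but also 5 in J82. Against the floor of 3 reads in both other lines, AJAP1 was 113.5-fold, NPAS3 15.05-fold and LOC284757 11.8-fold higher.

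CircRNAs found in 1 library were 395 in SV-HUC-1, 343 in J82 and 237 in T24, of which 45, 38 and 15 had at least 10 reads. Of these single-library circRNAs, 42.5%, 37.9% and 41.4% had no circBase ID, against 7.22% of those in all 3 libraries. Of 101 circRNAs spanning 100 kb or more, 43 (42.6%) had no circBase ID and 28 were in 1 library, 17 of them in J82, 7 in T24 and 4 in SV-HUC-1. Of 10461 shorter ones, 13.5% had no ID and 9.05% were in 1 library. Among the wide ones were circRNAs of INPP4B (323 kb, 5 reads) and RBMS3 (306 kb, 7 reads) in J82, and of IMMP2L (675 kb, 7 reads) and RIMS1 (493 kb, 8 reads) in T24.

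CircRNAs lower in both cancer lines outnumbered those higher in both by 566 to 246, a ratio of 2.30 (exact 95% interval 1.98 to 2.68). This interval and the exact ones below treat circRNAs as independent, although they share host genes and libraries. They do not measure variation between libraries. Counting noise with the shared SV-HUC-1 library gave 48.4 lower and 26.0 higher in both, a surplus of 22.4 (3 to 46 over 100 simulated sets) against 320, which argues against noise as the whole surplus, but its ratio of 1.93 (1.09 to 3.00) takes in the observed one. Centring each comparison left a ratio of 1.88 (1.63 to 2.19), which argues against scale as the whole cause. With a filter on the reads of all 3 libraries together the ratio was 0.915 (0.757 to 1.11). A circRNA abundant in SV-HUC-1 alone passes the main filter in both comparisons, so the surplus may come from how circRNAs enter the comparison. The filter on the total in turn favours circRNAs higher in both, which gain reads in both cancer libraries. It therefore cannot decide whether the main filter made the surplus. A difference of both cancer lines from SV-HUC-1 cannot be told apart from each line standing apart from the others, with 1 library per line: 812 of 3330 circRNAs differed from it the same way in both others, against 709 of 3013 from T24 and 657 of 3162 from J82, with ratios of lower to higher of 1.445 and 2.80 that the filter of 30 reads also changed, to 159 lower and 265 higher from T24 and 191 lower and 171 higher from J82.

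The folds of host genes differed between chromosomes. In J82 the median log2 fold was 0.76 on chromosome 4 (86 host genes) and 0.59 on chromosome 12 (127), against -0.44 on chromosome 10 (115) and -0.61 on chromosome 22 (54). In T24 it was 0.68 on chromosome 4 and 0.49 on chromosome 11 (128), against -0.58 on chromosome 10 and -0.41 on chromosome 5 (134). The spread of the medians over 23 chromosomes (root mean square, weighted by host genes) was 0.271 in J82 and 0.277 in T24, above the 95th percentiles of 0.158 and 0.165 when host genes were shuffled 100000 times, and of 0.158 and 0.166 when they were shuffled within 10 bins of mean CPM, which argues against chance and abundance. Folds of neighbouring host genes correlated with r = 0.143 in J82 and 0.132 in T24, across genes that are not independent replicates, above the shuffled ranges (up to 0.0633 and 0.0602), and gains or losses of chromosomes or segments may underlie this, in the cancer lines or, where both lines differ alike as on chromosomes 4 and 10, in SV-HUC-1, but no DNA was measured and this stays open.

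Some host genes gave circRNAs that differed in opposite directions, each past 2-fold and called by the exact binomial test. Among host genes with 2 or more circRNAs compared, these were 27 of 871 in J82 and 24 of 849 in T24. Counts simulated with 1 fold per host gene gave 0.06 and 0.12 such host genes on average in 50 sets, which argues against counting noise around a shared fold. In T24, KLHDC4 had a circRNA with 112 reads against 50 in SV-HUC-1 (hsa_circ_0000724, ratio 2.61, 1.86 to 3.72) and another with 1 against 26 (hsa_circ_0040787, ratio 0.0449, 0.00109 to 0.273). What underlies the rest was not tested, and unequal amplification of single circRNAs stays open with 1 library per line.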
